A study of Mus musculus with 110 samples.

How the data were processed

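RNA sequencing libraries were made from mouse placentas and whole fetuses at E12.5 (E, embryonic day) and from placentas and fetal livers at E18.5. The conceptuses came from natural conception, from in vitro fertilisation (IVF), or from IVF followed by a trophectoderm biopsy of the blastocyst, in which cells are taken from the outer layer of the embryo that forms the placenta (IVF+TEBx). Per the labels' protocols, tissues were snap frozen, RNA was extracted with a column kit, and 4 µg of total RNA entered a stranded kit for polyadenylated RNA. Sequencing was on an Illumina NovaSeq instrument, per the labels' design text. The design text plans 30 libraries per tissue. The 110 libraries used here fall into 24 groups of 2 to 6, set by tissue, sex and mode of conception, and any others are not analysed here.

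The authors deposited 4 tables of read counts per gene, 1 per tissue, with whole-number counts that are not normalised. Per the submitters' processing notes, the tools included Trimmomatic 0.32, STAR 2.3.0e, featureCounts 1.5.0 and DESeq2, with the mouse build mm10. The annotation, the strand setting and the treatment of read pairs are not given in the sources used here. Among genes with 1 to 10 counts, 62.1% to 78.8% of the deposited count values of a library were even numbers, so the counts hold fewer independent fragments than their totals. The authors also deposited 24 sheets of comparisons, 1 per tissue, sex and pair of modes. Per the file headers, each gives a log2 fold change and an adjusted p-value per gene in the form of a DESeq2 result. The same sheets give a group mean for each arm as CPM (counts scaled to the library total), which the authors computed. Recomputed means matched these for 100% of the genes in most columns. The exceptions were male Natural E12.5 placentas (17.9%), male IVF fetuses (9.46%), female IVF+TEBx E18.5 placentas (21.9%) and every liver column (5.62% to 15.5%), so the sheets rest in part on other values or libraries than the count tables. The authors' deposited tables of comparisons were used only to set their counts of calls beside those made here.

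The tables listed 24525 genes for whole fetuses and livers, 24527 for E18.5 placentas and 25239 for E12.5 placentas. From 24 to 26 names in all tables but that of the E12.5 placenta had been turned into dates by spreadsheet software and name no gene. Between 96.5% and 97% of the names were found in the GENCODE vM21 annotation of GRCm38, the assembly that mm10 denotes, and coordinates are given from it. Library totals ran from 35.6 to 149 M counts for E12.5 placentas, 12.1 to 65.7 M for fetuses, 8.74 to 96.8 M for E18.5 placentas and 19.7 to 30.5 M for livers. No 2 libraries of a group were identical. The labels do not say which libraries share a litter or an animal, so p-values measure the spread between these samples, which may be smaller than that between litters.

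Each tissue was fitted separately in edgeR 4.0.16 under R 4.3.3, with genes kept by filterByExpr, TMM normalisation and the quasi-likelihood F-test over 6 groups of sex and mode. The main contrast was the mean of the female and the male differences between modes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values quoted for single genes come from this test unless stated. The difference between the sexes was tested as an interaction. For placentas, the difference between E18.5 and E12.5 in each contrast was tested in a joint fit of both tables. Those tables were deposited separately, so a difference in their upstream handling stays within that test. The test of E18.5 against E12.5 compares differences between modes, not levels. SE denotes the standard error of a log2 fold change, and CPM values are TMM-normalised with their SD over the libraries of both sexes.

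Before the data were examined, 49 lists of genes were fixed from textbook knowledge: 19 for every tissue and the others for the tissue they fit. They cover pathways, imprinted genes and markers of the cell types a sample could hold. From 27 to 31 lists were tested per tissue. Each list was compared with all other genes by camera (limma 3.58.1, inter-gene correlation preset to 0.01), and again with the correlation estimated from the data. The fry test was run beside it: its directional p asks whether a list's genes move one way on balance, without comparing them with other genes. Camera and fry p-values were adjusted over the lists of a comparison. A list's score in a library is the mean log2 CPM of its genes, with a prior count of 2. The tests, the contrasts, the lists and most alternatives were also chosen before the data were examined.

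Genes were named by a rule fixed at the same time. For each comparison, the 8 highest and the 8 lowest log2 fold changes among called genes could be named, given the same sign in both sexes, a mean of at least 1 CPM in an arm and a symbol that is not a gene-model name. Up to 4 members of each list, those with the smallest p, could be named too, as could the 8 genes with the smallest p of an interaction. Xist and Ddx3y were kept as a check of the sex labels. Genes whose copies share reads, such as the Prl3d, Psg, Pate, Hspa1, Cyp2d and Serpina1 families, have uncertain single-gene counts.

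On simulated IVF against Natural counts, edgeR found 62 to 74 of 100 genes changed 2-fold and 87 to 95 of 100 changed 4-fold. It called 6 to 9 unchanged genes, depending on the tissue, and DESeq2 25 to 42. The joint placental fit recovered 49 of 100 genes at 2-fold and 77 at 4-fold, with 13 unchanged genes called. Of 100 random sets per tissue, camera gave 0 to 2 and fry 2 to 7 an unadjusted p under 0.05. Such sets lack the correlation of real lists, so camera is untested on those.

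The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no low-count filter, a term for the replicate number, the libraries of only 2 arms, each sex alone, a 2-fold minimum, the stem of the library name as a random block, a term for the style of that name, and leaving out each library in turn. Scores with stems as a block were fitted in nlme 3.1.168. The style term was planned for E12.5 placentas only. Alternatives chosen after seeing the data added it in the other tissues and the joint placental fit, left out doubted libraries or added marker scores as covariates.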

Results

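Gene expression was measured by RNA sequencing in 110 mouse libraries: 26 placentas and 30 whole fetuses at stage E12.5 (E, embryonic day), and 29 placentas and 25 fetal livers at E18.5, close to birth. The design asks how IVF, and IVF with a trophectoderm biopsy of the kind used for preimplantation genetic testing, alter the conceptus relative to natural conception. For E12.5 placentas, 5, 3 and 4 females and 5, 5 and 4 males came from the IVF, IVF+TEBx and Natural groups. The same order was 6, 5 and 5 females and 4, 5 and 5 males for E12.5 fetuses, 4, 6 and 5 females and 5, 4 and 5 males for E18.5 placentas, and 5, 5 and 2 females and 4, 5 and 4 males for livers. The median library held 92.3 M counts for E12.5 placentas, 46.1 M for fetuses, 48.5 M for E18.5 placentas and 24.1 M for livers.

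The sex labels were checked with Xist, the RNA that silences 1 X chromosome in females, and the Y-linked gene Ddx3y. Whole fetuses separated cleanly, with 917 to 4270 CPM of Xist in females and 0.246 to 3.34 CPM in males. In male placentas, which also hold maternal decidua, 4 libraries stood apart from their groups. Xist reached 404 CPM in E12.5 male IVF replicate 5, 136 CPM in E12.5 male IVF+TEBx replicate 3, 374 CPM in E18.5 male IVF replicate 2 and 81.2 CPM in E18.5 male IVF+TEBx replicate 1. Ddx3y was present in the male IVF libraries among these, at 34.9 CPM in replicate 5 at E12.5 and 43.3 CPM in replicate 2 at E18.5.

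At E12.5, IVF placentas held less RNA of the spongiotrophoblast, the endocrine layer between the exchange zone and the maternal tissue. The prolactin-family hormone gene Prl8a8 (chromosome 13, 27506968 to 27513217) stood at 45.9 ± 63.3 CPM (SD, n = 10) in IVF placentas and 418 ± 289 CPM (n = 8) in Natural placentas, a log2 change of -3.23 (SE 0.83, adjusted p = 0.0383). Its relative Prl2b1 (chromosome 13, 27383339 to 27390846) fell from 1540 ± 488 to 682 ± 346 CPM (log2 change -1.16, SE 0.29, adjusted p = 0.0345). Pregnancy-specific glycoprotein genes, which share reads within their family, fell as well: Psg17 by 2.11 on the log2 scale, Psg19 by 1.72, Psg21 by 2.60 and Psg23 by 2.77. Of the 22 spongiotrophoblast genes measured, 7 fell, 1 rose (Ceacam9, log2 change 1.14, named after its values were seen) and the others did not pass; adjusted over the list alone, 15 fell and 1 rose. The list's median log2 change was -1.51, with a camera adjusted p of 1.12e-08 against all other genes and an adjusted p = 0.677 with an estimated correlation. Its fry directional adjusted p was 0.0487. Its score averaged 8.25 ± 0.42 in Natural, 6.55 ± 0.93 in IVF and 6.27 ± 1.71 in IVF+TEBx placentas. Markers of the visceral yolk sac, a nearby membrane, had a median log2 change of 2.27 with 0 of 18 called. Their score differed by 0.35 (SE 1.36) for both IVF arms.

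**Figure D1:**
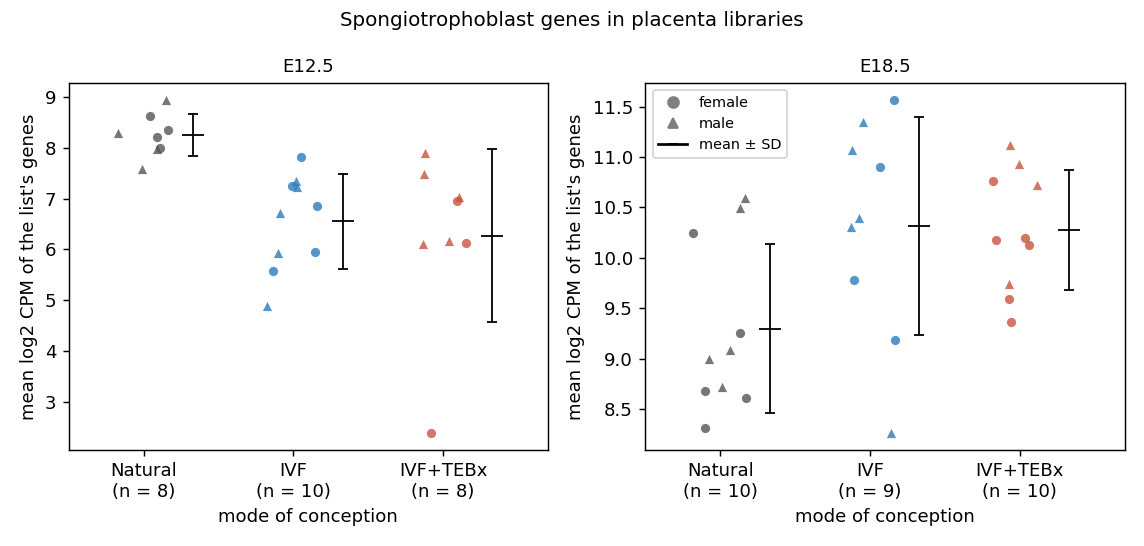
Spongiotrophoblast score, the mean log2 CPM of the list's genes (vertical axis), of each placenta by mode of conception (horizontal axis) at E12.5 and at E18.5. Points are libraries with sexes by marker, and bars are mean ± SD. Means were 8.25 in Natural, 6.55 in IVF and 6.27 in IVF+TEBx placentas at E12.5, and 9.30, 10.31 and 10.27 at E18.5.

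Other gene groups of the IVF placenta at E12.5 had 3 or fewer members called each. Among trophoblast giant cells, which line the maternal blood spaces, Ctsq fell by 1.64 and Prl7a2 by 1.96 on the log2 scale, while 17 of the 19 list members did not pass. That list had 6 members that rose and 3 that fell when adjusted over the list alone, and a camera adjusted p of 0.788. Genes of stress and of the interferon response moved in opposite directions: Hspa1a (log2 change 2.43), Hspa1b (2.28) and Hsph1 (1.01), genes of heat-shock chaperones, rose, and the antiviral genes Rsad2 (-1.04, from 104 ± 21.6 to 50.7 ± 16.3 CPM), Bst2 (-0.72) and Oas1a (-0.60) fell. These were 3 of 19 heat-shock and immediate early genes (camera adjusted p = 0.00402; adjusted p = 0.709 with an estimated correlation) and 3 of 16 interferon genes (0.00201; adjusted p = 0.829 with an estimated correlation). Imprinted genes moved singly. The maternally expressed Zim1 (chromosome 7, 6671269 to 6696450) fell by 1.45 (SE 0.28, adjusted p = 0.0124) and the transporter gene Slc22a18 (chromosome 7, 143473736 to 143499334) by 1.19, as 2 of 32 maternally expressed genes, and the paternally expressed Zrsr1 rose by 0.72 as 1 of 28. Pcna, the sliding clamp of DNA replication, rose by 0.41 and Cox7a2 of the respiratory chain by 0.29. The amino acid transporter Slc38a1 fell by 0.41, and the clock genes Bhlhe41 and Per3 by 0.73 and 0.56. The X-linked homeobox gene Rhox13 (X, 38121219 to 38129967) was near 0 in Natural placentas (0.067 ± 0.0482 CPM) and reached 5.54 ± 6.74 CPM in IVF placentas (adjusted p = 0.00384). Other than Ceacam9, every gene named for IVF against Natural E12.5 placentas lay beyond the Natural median in 10 of 10 IVF libraries. Further lists with a camera adjusted p under 0.05 were oxidative phosphorylation (median 0.13, 1 of 27 called, 0.0001), cell cycle (0.25, 1 of 30, 0.00224), labyrinth (-0.45, 1 of 19, 0.000981), nutrient transporters (-0.20, 1 of 24, 0.0011; fry adjusted p = 0.0487) and megakaryocytes (-0.48, 0 of 12, 0.0159). With an estimated correlation these stood at 0.709, 0.845, 0.829, 0.677 and 0.829.

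The test called 501 of 17799 genes in this comparison (181 higher, 320 lower). The count depended on single placentas. It was 53 without male Natural replicate 2, 126 without female Natural 1, 195 without male Natural 3, 227 without female Natural 4, 256 without female IVF 4, 260 without female IVF 1, 279 without female Natural 3, 284 without female IVF 3, 294 without male IVF 4, 300 without male Natural 1 and 832 without female IVF 2. It was 2015 with 3 doubted placentas left out (an alternative added after seeing the data), 1561 in DESeq2 and 1497 when only the 2 arms were fitted. The balance of directions depended on the fit as well: 812 rose and 685 fell with the 2 arms, 815 and 746 in DESeq2, 1111 and 904 with the 3 doubted placentas left out. A term for the style of the library name (a leading four-digit number in 5 of 10 IVF, 3 of 8 IVF+TEBx and 0 of 8 Natural placentas) gave 627 calls, 355 higher and 272 lower. Only 323 of the 501 calls were among them, and 21 of the 32 named genes. Males alone gave 0 calls in edgeR, with 1523 genes at an unadjusted p under 0.05, and females alone gave 1.

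After IVF and biopsy, more genes passed at E12.5. Spongiotrophoblast genes again fell: Prl8a8 from 418 ± 289 to 38.8 ± 39.1 CPM (log2 change -3.72, SE 0.98, adjusted p = 0.0179, n = 8 and 8), Prl8a9 by 1.66 and Prl2b1 by 1.38. Of the 22 members 13 fell and Ceacam9 rose; adjusted over the list alone, 15 fell and 1 rose. Their median log2 change was -1.71 (camera adjusted p = 2.89e-08; adjusted p = 0.515 with an estimated correlation). Giant cell genes went both ways. Genes of the placental lactogen family made by early, parietal giant cells rose, with Prl3d1 at 1340 ± 3020 CPM against 44.5 ± 30.0 CPM (log2 change 4.46, SE 0.92, adjusted p = 0.00615) and Prl3d2 and Prl3d3, near-identical copies whose reads cannot be told apart with certainty, at 5.02 and 4.69. Ctsq, a cathepsin of the giant cells that line the labyrinth's blood sinusoids, fell by 2.39 (SE 0.45, adjusted p = 0.00460). In all, 7 of 19 giant cell genes rose and 6 fell, and the camera adjusted p was 0.792. Yolk sac markers had a median of 2.96 with 0 of 18 called.

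Genes of oxidative phosphorylation rose in IVF+TEBx placentas at E12.5 in 14 of 27 cases (17 adjusted over the list alone) and none fell, by small amounts such as 0.39 for Ndufs3 and Cox7a2 and 0.36 for Atp5c1. The list's camera adjusted p was 5.49e-10 (adjusted p = 0.490 with an estimated correlation). Of the 30 cell cycle genes 5 rose, among them the replication licensing gene Cdc6 (log2 change 1.17) and the mitotic kinase gene Cdk1 (0.83), with 11 adjusted over the list alone (camera adjusted p = 4.34e-07; adjusted p = 0.722 with an estimated correlation). Heat-shock genes rose in 6 of 19 cases, with Hsph1 at 1.20 and Hsp90aa1 at 0.74. The serine synthesis genes Phgdh and Psat1 rose by 1.12 and 1.09, and the glycolytic genes Pgk1, Ldha and Eno1 by 0.64, 0.58 and 0.62. The interferon genes Rsad2 (-1.20), Bst2 (-0.82) and Oas1a (-0.76) fell, as 3 of 16 (camera adjusted p = 8.67e-05; adjusted p = 0.722 with an estimated correlation). Among imprinted genes, Zim1 fell by 2.05 (SE 0.31, adjusted p = 0.00404), Slc22a18 by 1.19 and the growth restrictor Cdkn1c by 0.63, while H19 rose by 0.91; 3 of 32 maternally expressed genes fell and 2 rose, and 4 of 28 paternally expressed genes rose. The DNA methyltransferase gene Dnmt3a fell by 0.58. Transporter genes fell in 3 of 24 cases, with Slc38a1 at -0.56, the cholesterol exporter Abcg1 at -1.16 and the cationic amino acid carrier Slc7a1 at -0.58, and 1 rose. Clock genes fell in 4 of 16 cases, including Bhlhe41 (-0.89) and Per3 (-0.74). Flt1, a receptor for vascular growth factor, fell by 1.24, fibronectin (Fn1) by 0.91 and the glycogen cell marker Aldh1a3 by 1.70. Eomes, a gene of natural killer cells and of trophoblast stem cells, rose by 2.16.

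The biopsy comparison with Natural called 2387 of 17799 genes at E12.5 (1407 higher, 980 lower). The count was 929 without female IVF+TEBx replicate 1, a placenta with a spongiotrophoblast score of 2.38, 1356 without male Natural 2 and 1433 without female Natural 1, and 1532 with 3 doubted placentas left out after seeing the data. Genes that fell were the larger part in other fits: 904 rose and 1080 fell in limma-voom, 690 and 842 with the 3 placentas left out, and 420 and 509 without female IVF+TEBx replicate 1. Females alone gave 1026 calls and males alone 0 in edgeR, with 1496 genes at an unadjusted p under 0.05 in males. The difference between the sexes itself gave 0 calls, with 549 genes at an unadjusted p under 0.05 (1746 without female IVF+TEBx 3 and 1658 without female IVF+TEBx 2, where chance gives 890) and 1 call in DESeq2. Genes named for this comparison lay beyond the Natural median in all 8 IVF+TEBx placentas, or in 7 for Cdkn1c, Eno1, Slc7a1 and Flt1.

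Between IVF+TEBx and IVF placentas at E12.5, the comparison that isolates the biopsy, no gene was called. The edgeR test had 834 of 17799 genes at an unadjusted p under 0.05, where 890 would arise by chance, and DESeq2 and limma-voom also called 0. That unadjusted count was 2867 without female IVF+TEBx replicate 3, 1674 without female IVF+TEBx 2, 1366 without male IVF 4, 1260 without female IVF 3 and 1309 without the 3 doubted placentas. It was 1677 in females alone and 253 in males alone, so it does not bound the effect of the biopsy. Zim1 stood at 24.3 ± 12.6 CPM against 34.4 ± 19.8 CPM (log2 change -0.60, SE 0.29, adjusted p = 0.906). Oxidative phosphorylation genes had a median log2 change of 0.11, with Ndufs3 at 0.24 (SE 0.08, adjusted p = 0.906), and a camera adjusted p of 3.55e-09 (adjusted p = 0.656 with an estimated correlation). Cell cycle genes had a median of 0.24 (2.07e-06; adjusted p = 0.888 with an estimated correlation).

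Between IVF and Natural whole fetuses at E12.5, edgeR called a single gene of 17645: Ppp1r10 (chromosome 17, 35916434 to 35932283), which encodes a regulatory subunit of protein phosphatase 1, rose from 97.5 ± 6.47 to 131 ± 15.0 CPM (n = 10 and 10, log2 change 0.42, SE 0.07, adjusted p = 0.0249) and lay above the Natural median in 10 of 10 IVF fetuses. At an unadjusted p under 0.05 there were 2160 genes against 882 by chance, and DESeq2 called 140 and limma-voom 2. The edgeR count became 0 without any of 12 single fetuses and 6 without male IVF 4. No list had a member called, while camera called 15 of 29 lists and 0 with an estimated correlation. Lens genes had a median log2 change of -1.39 (camera adjusted p = 3.69e-12; adjusted p = 0.269 with an estimated correlation) and neutrophil genes one of -1.37 (5.47e-09; adjusted p = 0.269 with an estimated correlation), with 8 neutrophil genes lower adjusted over the list alone. Early stage genes had a median of 0.31 with 3 of 16 higher adjusted over the list alone (camera adjusted p = 9.04e-06; adjusted p = 0.275 with an estimated correlation). Cartilage genes had a median of -0.30 with 1 higher and 3 lower of 21 (0.000873; adjusted p = 0.466 with an estimated correlation).

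Fetuses from biopsied blastocysts held less RNA of cartilage and bone genes than Natural fetuses, and more of genes that decline as development proceeds. Matn1 (chromosome 4, 130944385 to 130955475), which encodes the cartilage protein matrilin 1, fell from 6.16 ± 3.48 to 0.796 ± 0.565 CPM (n = 10 and 10, log2 change -2.95, SE 0.42, adjusted p = 0.000418). Its relative Matn4 fell from 44.7 ± 16.5 to 14.5 ± 6.59 CPM (-1.60, SE 0.23, adjusted p = 0.000444) and the collagen gene Col9a3 by 1.23. Of 21 cartilage and bone genes 9 fell and none rose; adjusted over the list alone, 13 fell and 1 rose. The median log2 change was -0.76. This was the only list of any comparison whose camera call held with an estimated correlation (adjusted p = 8.22e-12; adjusted p = 0.0345 with an estimated correlation), and its fry adjusted p was 0.0001. The RNA-binding genes Igf2bp1 (chromosome 11, 95957163 to 96005940), Lin28b and Lin28a (chromosome 4, 134003330 to 134018841), which mark early stages, rose by 0.53, 0.85 and 1.56 on the log2 scale; 6 of 16 early stage genes rose (10 adjusted over the list alone), with a camera adjusted p of 4.27e-09 and an adjusted p = 0.141 with an estimated correlation. Igdcc3 rose by 1.44 and the DNA methyltransferase gene Dnmt3b, itself an early stage gene, by 0.36.

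**Figure D2:**
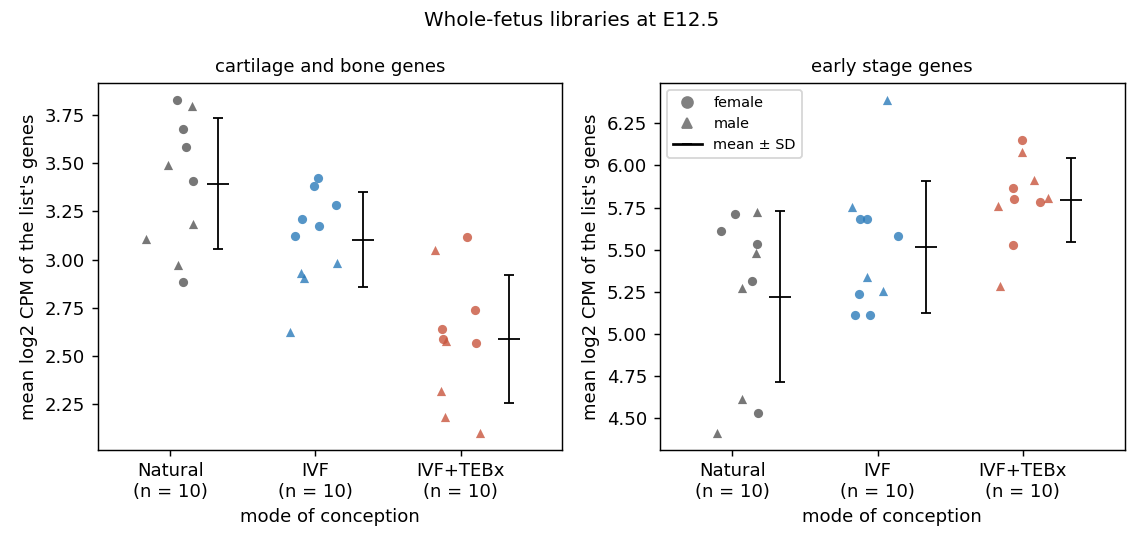
Cartilage and bone score and early stage score, each the mean log2 CPM of the list's genes (vertical axes), of 30 whole fetuses at E12.5 by mode of conception (horizontal axis). Points are libraries with sexes by marker, and bars are mean ± SD. Cartilage means were 3.39 in Natural, 3.10 in IVF and 2.59 in IVF+TEBx fetuses, and early stage means were 5.22, 5.51 and 5.80.

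Connective tissue collagens fell in the same fetuses, with Col6a1 at -0.87 and Col6a2 at -0.74, as 7 of 17 matrix genes (10 adjusted over the list alone; camera adjusted p = 4.54e-08; adjusted p = 0.217 with an estimated correlation). Skeletal muscle genes fell in 7 of 22 cases (10 adjusted over the list alone), among them the embryonic and perinatal myosin genes Myh3 (-0.90) and Myh8 (-1.09) and the light chain gene Mylpf (-0.93), with a camera adjusted p of 2.40e-06 and an adjusted p = 0.295 with an estimated correlation. The keratin genes Krt14 (-1.16), Krt15 (-1.03) and Krt5 (from 102 ± 27.3 to 51.3 ± 29.2 CPM) of the basal epidermis fell as 3 of 14, in a list with a median of -0.19 (camera adjusted p = 0.000641; adjusted p = 0.290 with an estimated correlation). Crystallin genes of the lens fell in 6 of 15 cases (12 adjusted over the list alone), with Cryba4 at -2.27 and Crygd at -3.41 from levels of 2.95 and 3.18 CPM (camera adjusted p = 3.96e-10; adjusted p = 0.217 with an estimated correlation). The neuronal transcription factor genes Neurod2 and Neurod6 fell by 2.26 and 3.12, as 2 of 21 neuronal genes (camera adjusted p = 0.0286; adjusted p = 0.641 with an estimated correlation). Dcn, which encodes the matrix protein decorin, fell by 1.06, Mmp9, a matrix protease gene of neutrophils, by 0.97, and the germline gene Tdrd1 by 0.84. Cardiac genes had a median log2 change of 1.11 with 0 of 16 called (camera adjusted p = 0.00190; adjusted p = 0.556 with an estimated correlation), and the 37 Hox genes gave 0 calls. The cell cycle list also had 0 of 30 called, with a median of 0.16, a camera adjusted p of 7.72e-06 (adjusted p = 0.259 with an estimated correlation) and a fry adjusted p of 0.0297. The genes named so far for this comparison lay beyond the Natural median in 10 of 10 IVF+TEBx fetuses, or in 9 for Myh8 and Krt5.

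In this comparison 598 of 17645 genes were called, 151 higher and 447 lower. The count was 296 without male Natural replicate 1, 324 without female Natural 1, 344 without female IVF+TEBx 3, 375 without female Natural 2 and 377 without male IVF+TEBx 4. It was 614 in limma-voom, and 41 there with libraries that share a name stem treated as related. Females alone gave 335 calls and males alone 0 in edgeR (853 genes at an unadjusted p under 0.05 in males), and the difference between the sexes gave 0 calls with 605 genes at an unadjusted p under 0.05 and 3 calls in DESeq2.

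Between IVF+TEBx and IVF fetuses, edgeR called 0 genes, with 1711 at an unadjusted p under 0.05 against 882 by chance; DESeq2 called 12, limma-voom 0, and the female contrast alone 7. Without male IVF+TEBx replicate 2, edgeR called 4. Cartilage genes were lower here too, with 8 of 21 passing only when adjusted over the list alone. Col9a3 stood at 36.6 ± 18.7 against 71.3 ± 19.1 CPM (log2 change -0.93, SE 0.23, adjusted p = 0.278, and 0.00501 over the list alone), Matn1 at -1.45 (0.336 and 0.00698), Matn4 at -0.87 and Runx2, the regulator of bone formation, at -0.56. Their camera adjusted p was 6.09e-08 (adjusted p = 0.191 with an estimated correlation) and their fry adjusted p 0.0366. Lin28b stood at 41.4 ± 14.4 against 28.3 ± 4.77 CPM (log2 change 0.52, adjusted p = 0.360), and the glycolytic gene Pgk1 at 97.0 ± 30.1 against 61.5 ± 15.8 CPM (0.64, adjusted p = 0.328). Glycolysis genes had a median log2 change of 0.47 (camera adjusted p = 6.16e-08; adjusted p = 0.879 with an estimated correlation).

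At E18.5 the spongiotrophoblast difference had the opposite sign, in libraries whose names differ in style between the modes. A name with a leading four-digit number was carried by 8 of 9 IVF, 9 of 10 IVF+TEBx and 0 of 10 Natural placentas. In IVF placentas Prl8a8 rose to 5380 ± 3340 CPM (n = 9) from 2010 ± 1440 CPM (n = 10; log2 change 1.47, SE 0.42, adjusted p = 0.0253), Prl3c1 from 9.08 ± 5.30 to 40.9 ± 33.9 CPM (2.17, SE 0.45, adjusted p = 0.00562), and Psg25 by 1.46. Of 22 spongiotrophoblast genes 11 rose and none fell, 16 adjusted over the list alone, with a median of 1.20 (camera adjusted p = 1e-06; adjusted p = 0.553 with an estimated correlation; fry adjusted p = 0.0565). The prolactin-family genes Prl7a1 and Prl7a2 of giant cells rose by 2.69 and 2.25, while the cathepsin gene Ctsr fell by 0.66; 6 of 19 giant cell genes rose and 2 fell. In the labyrinth, where exchange with maternal blood takes place, Gcm1 (chromosome 9, 78051924 to 78065624), the transcription factor gene that starts its branching, rose from 3.39 ± 4.55 to 15.2 ± 8.56 CPM (2.29, SE 0.42, adjusted p = 0.00282). The fusion protein genes Synb and Syna rose by 1.38 and 1.33 and the lactate carrier Slc16a3 by 1.07, as 4 of 19 labyrinth genes. Glycogen phosphorylase (Pygl) and glycogen synthase (Gys1) genes rose by 0.90 and 0.39.

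Sterol and lipid synthesis genes were also higher in IVF placentas at E18.5. Hmgcr (chromosome 13, 96648967 to 96670936), the rate-limiting enzyme of cholesterol synthesis, rose from 65.4 ± 4.89 to 87.4 ± 9.26 CPM (log2 change 0.42, SE 0.08, adjusted p = 0.00281), Insig1 by 0.58, Sqle by 0.39 and Cyp51 by 0.44, as 4 of 20 (7 adjusted over the list alone; camera adjusted p = 0.000459; adjusted p = 0.437 with an estimated correlation). Of 18 fatty acid synthesis genes 4 rose, with the desaturase gene Fads2 at 1.06 and Srebf1 at 0.39. The endoplasmic reticulum chaperone gene Hyou1 rose by 0.75 and the glutathione-degrading enzyme gene Chac1 fell by 1.93, in a stress list with 7 of 20 higher and 1 lower (camera adjusted p = 0.00100; adjusted p = 0.523 with an estimated correlation). Imprinted genes that rose were the paternally expressed Usp29 (chromosome 7, 6730578 to 6967219; 1.04), Sgce (0.94), Slc38a4 (0.55) and Zrsr1 (0.48), as 4 of 30, and, among 2 of 31 maternally expressed ones, Slc22a18 (2.04); 2 of those 31 fell, and their median was -0.25. Dcn fell by 1.61. The clock genes Per2 (-0.93), Nr1d1 (-1.03) and Nr1d2 (-0.54) fell as 3 of 16, and the immediate early gene Fos by 1.08. Rsad2 rose by 0.67, Vegfa by 0.44, Ldha by 0.56 and Flt1 by 1.36.

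Erythroid and macrophage transcripts were higher in the IVF placentas at E18.5. The red cell anion exchanger gene Slc4a1 rose from 8.28 ± 4.05 to 33.7 ± 33.3 CPM (log2 change 1.95, SE 0.38, adjusted p = 0.00404), Spta1 by 2.20 and Gypa by 1.97, as 7 of 16 erythroid genes (camera adjusted p = 0.000119; adjusted p = 0.437 with an estimated correlation). Macrophage genes rose in 5 of 16 cases (11 adjusted over the list alone), including Aif1 (1.46) and Csf1r (0.50). Other immune lists were not called: neutrophil genes rose in 2 of 13 cases (camera adjusted p = 0.243), interferon genes rose in 2 and fell in 1 of 16 (0.607), and natural killer cell genes rose in 2 of 12 (0.158). The chemokine genes Ccl3, Ccl4 and Cxcl2 rose by 4.75, 5.34 and 5.26, Acod1 of activated macrophages by 5.86 and the acute phase gene Saa3 by 5.40, with wide spread (Saa3 34.1 ± 58.7 CPM). Yolk sac genes were higher too: Trf reached 900 ± 644 against 257 ± 89.5 CPM and Alb 14.6 ± 20.8 against 1.14 ± 1.26 CPM, as 4 of 18 (14 adjusted over the list alone), with a median log2 change of 2.57 and a camera adjusted p of 0.0153 (adjusted p = 0.755 with an estimated correlation). Genes that fell most included the protease gene Ctsk (-3.51, from 90.6 ± 87.1 to 8.37 ± 7.36 CPM), Ly6d (-2.88), Rxfp1, a relaxin receptor gene (-3.32), and Khdc3 (-2.95). The genes named for this comparison lay beyond the Natural median in 8 or 9 of 9 IVF placentas, except Cxcl2 and Flt1 (7), Saa3 and Alb (6) and Syna (5).

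The IVF comparison at E18.5 called 2175 of 16790 placental genes, 1237 higher and 938 lower. Without a single placenta the count was 1061 (female IVF replicate 3), 1210 (female IVF 2), 1264 (male Natural 5), 1294 (male Natural 4), 1392 (female Natural 3), 1402 (male IVF 3) and 1424 (female Natural 4). DESeq2 called 3295, limma-voom with name stems 1047 (485 higher, 562 lower), limma-voom 801 higher and 841 lower, females alone 59 and males alone 25. A term for the style of the library name, added after seeing the data, left 0 calls, with 1552 genes at an unadjusted p under 0.05. Prl8a8 went from 1.47 (SE 0.42) to 0.99 (SE 0.75), Gcm1 from 2.29 (SE 0.42) to 1.92 (SE 0.67) and Hmgcr from 0.42 (SE 0.08) to 0.16 (SE 0.13). The calls ended because the term, which rests on 1 IVF and 1 IVF+TEBx placenta, raised the median SE from 0.18 to 0.32, and because these folds shrank. The difference between the sexes gave 0 calls in edgeR, with 418 genes at an unadjusted p under 0.05 and 1 call in DESeq2.

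Biopsied placentas at E18.5 were compared with the same Natural placentas. Prl8a8 rose to 4720 ± 2660 CPM (n = 10 and 10, log2 change 1.31, SE 0.41, adjusted p = 0.0453), Prl3c1 by 1.82 and Prl2b1 by 1.15; 4 of 22 spongiotrophoblast genes rose, 10 adjusted over the list alone, with a median of 0.97 (camera adjusted p = 5.16e-07; adjusted p = 0.408 with an estimated correlation). Prl7a1 and Prl7a2 rose by 2.91 and 2.01, and Ctsr and Ctsq fell by 0.79 and 0.71. Gcm1 rose to 16.1 ± 7.24 CPM (2.22, SE 0.41, adjusted p = 0.00402), Synb by 1.39 and Slc16a3 by 0.98. Hmgcr rose to 90.5 ± 12.0 CPM (0.48, SE 0.07, adjusted p = 0.00160), Insig1 by 0.55 and Sqle by 0.36, as 4 of 20 sterol genes (camera adjusted p = 0.000177; adjusted p = 0.267 with an estimated correlation). The desaturase gene Scd2 rose by 0.75, Fads2 by 0.98 and Srebf1 by 0.50, as 5 of 18 fatty acid synthesis genes. Slc22a18 rose by 2.09, Sgce by 0.87, Usp29 by 0.66 and Slc38a4 by 0.53. Slc4a1 and Spta1 rose by 1.38 and 1.58, as 4 of 16 erythroid genes (camera adjusted p = 0.000342; adjusted p = 0.340 with an estimated correlation). Il2rb and Eomes of uterine natural killer cells rose by 0.83 and 1.21 as 2 of 12. Macrophage genes rose in 1 of 16 cases (3 adjusted over the list alone; median 0.57, camera adjusted p = 0.0312; adjusted p = 0.658 with an estimated correlation), against 5 of 16 for IVF. Rsad2 rose by 0.87, Pygl by 0.78 and Hyou1 by 0.71, while Chac1 fell by 1.28, Per2 by 0.69 and Fos by 0.94. Yolk sac genes had a median of 2.71, with Trf (1.94) and Alb (3.95) among 3 of 18 that rose. The keratin gene Krt15 rose by 5.26, and the early embryo gene Crxos fell by 2.08. These genes lay beyond the Natural median in 8 to 10 of 10 biopsied placentas, except Alb and Krt15 (7).

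The count of the biopsy comparison with Natural was 1559 (811 higher, 748 lower), and it moved with single placentas: 645 without male IVF+TEBx replicate 4, 783 without male IVF+TEBx 3, 832 without male Natural 5, 883 without male Natural 4, 884 without female Natural 3, 961 without female Natural 4, 1004 without female IVF+TEBx 3, 1017 without male Natural 2, 1038 without male IVF+TEBx 2 and 3068 without male IVF+TEBx 1, the placenta with 81.2 CPM of Xist. DESeq2 called 2498, limma-voom 716 higher and 959 lower, females alone 61 and males alone 3. With the term for the style of the library name 10 genes were called, 4 of them among the 1559, and Gcm1 went from 2.22 (SE 0.41) to 1.84 (SE 0.68) and Hmgcr from 0.48 (SE 0.07) to 0.22 (SE 0.12). The sexes did not differ in any gene in edgeR (680 at an unadjusted p under 0.05) or DESeq2 (0 calls).

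Between IVF+TEBx and IVF placentas at E18.5, edgeR and limma-voom called 0 genes, DESeq2 1, and 641 of 16790 had an unadjusted p under 0.05 where chance gives 840. Decidual genes, from the maternal side, had 5 of 17 higher adjusted over the list alone and a median of 0.71 (camera adjusted p = 6.29e-06; adjusted p = 0.292 with an estimated correlation). Hand2 stood at 44.8 ± 23.3 against 19.1 ± 10.6 CPM (log2 change 1.32, SE 0.39, adjusted p = 1, and 0.0301 over the list alone) and Hoxa10 at 1.51. The granzyme gene Gzmd of uterine natural killer cells stood at 1.91, in a list with 5 of 12 higher adjusted over the list alone and a median of 0.83 (camera adjusted p = 0.00982; adjusted p = 0.797 with an estimated correlation), and the macrophage gene Marco at -2.57 (0.0439 and 0.0485 over their lists alone). Macrophage genes had a median of -0.42 (camera adjusted p = 0.00124; adjusted p = 0.797 with an estimated correlation), fibroblast genes one of 0.54 (0.00257; adjusted p = 0.797 with an estimated correlation) and cell cycle genes one of -0.12 (0.00124; adjusted p = 0.850 with an estimated correlation).

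In fetal livers at E18.5, libraries of the IVF groups held more RNA of dividing and red blood cells and less of fat oxidation. Here too the names differ in style between the modes: 8 of 9 IVF, 9 of 10 IVF+TEBx and 0 of 6 Natural livers have a leading four-digit number. Mki67 (chromosome 7, 135689784 to 135716361), a marker of cycling cells, rose from 1230 ± 339 CPM (n = 6) to 2370 ± 599 CPM (n = 9; log2 change 0.90, SE 0.17, adjusted p = 0.00300), Cenpf by 0.89 and Cenpe by 0.80, and all 30 cell cycle genes measured rose (median 0.66, camera adjusted p = 3.04e-19; adjusted p = 0.411 with an estimated correlation). The red cell membrane genes Epb42 (chromosome 2, 121017891 to 121037072; 1.03), Ank1 (0.96), Kel (0.87) and Slc4a1 (chromosome 11, 102348824 to 102366203; 0.86) rose as 13 of 16 erythroid genes (14 adjusted over the list alone; camera adjusted p = 2.13e-09; adjusted p = 0.411 with an estimated correlation). Of 23 genes of fatty acid oxidation and other targets of PPAR alpha, the liver's fasting receptor, 18 fell and none rose, 21 adjusted over the list alone (median -0.86, camera adjusted p = 6.98e-12; adjusted p = 0.411 with an estimated correlation). Ehhadh (chromosome 16, 21761287 to 21787807), an enzyme of peroxisomal oxidation, fell from 228 ± 75.6 to 77.6 ± 34.9 CPM (-1.63, SE 0.30, adjusted p = 0.00245), Vnn1 by 1.81 and the mitochondrial dehydrogenase gene Acadvl by 0.68. The hormone gene Fgf21 (chromosome 7, 45613886 to 45615490) had 8 counts over 9 IVF livers and 224 over 6 Natural livers.

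**Figure D3:**
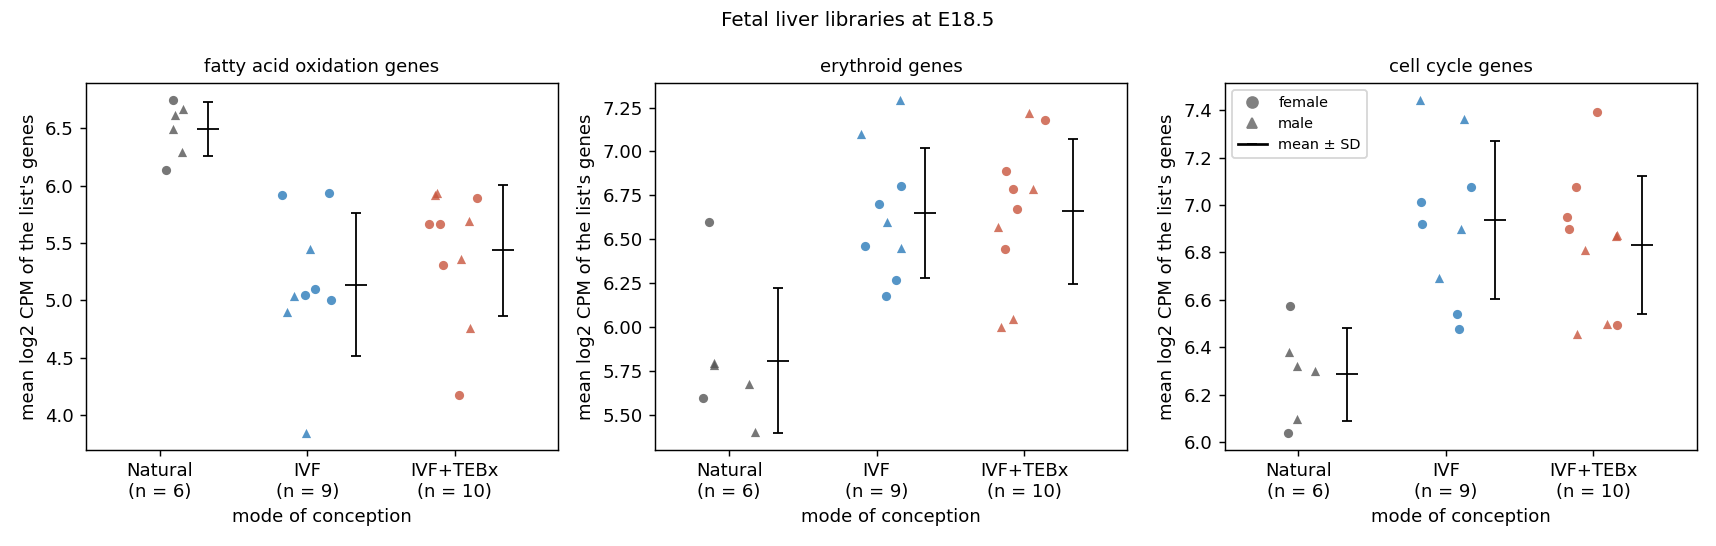
Scores of fatty acid oxidation, erythroid and cell cycle genes, each the mean log2 CPM of the list's genes (vertical axes), of 25 fetal livers at E18.5 by mode of conception (horizontal axes). Points are libraries with sexes by marker, and bars are mean ± SD. Fatty acid oxidation means were 6.49 in Natural, 5.14 in IVF and 5.44 in IVF+TEBx livers, and erythroid means were 5.81, 6.65 and 6.66.

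Genes of the mature hepatocyte fell in IVF livers. Of 25 such genes 9 fell (16 adjusted over the list alone), among them the glycogen synthase gene Gys2 (-0.60) and Aldob (-0.85), with a camera adjusted p of 6.52e-07 and an adjusted p = 0.465 with an estimated correlation. Apolipoprotein genes fell, with Apoc4 at -1.14, Apoa2 at -0.55 and Apoa4 at -3.80, as did Mttp (-0.45), which loads fat onto lipoproteins; 12 of 22 lipoprotein genes fell and 1 rose. The bile salt and phospholipid transporter genes Slco1b2 (-1.75) and Abcb4 (-0.61) fell among 7 of 18. Respiratory chain genes fell in 11 of 27 cases, with Cox4i1 at -0.44, Cox5a at -0.45 and Uqcrq at -0.47. Interferon genes fell in 9 of 16 cases, with Isg15 (chromosome 4, 156199424 to 156200818) at 7.87 ± 7.22 against 45.1 ± 37.3 CPM (-2.66, SE 0.59, adjusted p = 0.00527), Bst2 at -1.17 and Oasl2 at -1.66 (camera adjusted p = 7.79e-05; adjusted p = 0.465 with an estimated correlation). The gluconeogenic gene Pck1 fell by 3.38, the growth factor binding gene Igfbp1 by 1.95 and the stress gene Trib3 by 2.26. Of 30 maternally expressed imprinted genes 5 rose and 2 fell (camera adjusted p = 0.143), and of 28 paternally expressed ones 5 rose and 4 fell (0.268). Among those that rose, in the Dlk1 to Meg3 region on chromosome 12, were Dlk1 by 1.14, Rtl1 by 1.76, Rian by 0.95 and the non-coding Meg3 (chromosome 12, 109541001 to 109571726) by 0.89, from 173 ± 52.7 to 333 ± 66.5 CPM. The DNA methylation genes Dnmt1 and Uhrf1 rose by 0.70 and 0.72, in a list with 6 of 15 higher. Serpina6 (chromosome 12, 103646630 to 103657212), which encodes the carrier of corticosteroids in blood, rose from 17.5 ± 30.8 to 571 ± 589 CPM (5.18, SE 1.27, adjusted p = 0.00835), and Hamp (chromosome 7, 30942368 to 30944032), the gene of the iron hormone hepcidin, from 8.99 ± 5.58 to 77.7 ± 76.5 CPM (3.10, SE 0.84, adjusted p = 0.0136). Of genes expressed in fetal hepatoblasts Spink1 rose from 11.7 ± 12.7 to 35.0 ± 13.2 CPM while Akr1c18 and Cyp3a16 fell by 3.18 and 0.97. The genes named so far for IVF livers lay beyond the Natural median in 9 of 9, or in 8 for Pck1.

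Pancreas genes separated 2 of the Natural livers from the rest. The pancreas score was 2.48 in female Natural replicate 3 and 1.19 in male Natural replicate 4, and -2.29 to -0.604 in the other 23 livers. The pancreatic protease gene Cela3b stood at 2.39 ± 3.58 CPM in Natural, 0.168 ± 0.0898 in IVF and 0.247 ± 0.165 in IVF+TEBx livers, and 14 of 21 pancreas and gut genes fell in IVF livers. IVF against Natural called 3101 of 15344 liver genes (1646 higher, 1455 lower). The count was 239 without those 2 livers and 38 with the erythroid score as a covariate, both settings added after seeing the data. It was 398 without female Natural replicate 3, which leaves a lone female Natural liver assumed to vary like the other groups, and 2038 without male IVF 2. Directions turned with the calls: 7 rose and 31 fell with the erythroid score, 91 and 148 without the 2 livers, and 193 and 205 without female Natural replicate 3. A term for the style of the library name, also added after seeing the data, left 0 calls, with 1003 genes at an unadjusted p under 0.05. Mki67 went from 0.90 (SE 0.17) to 0.41 (SE 0.24), Epb42 from 1.03 (SE 0.18) to 0.44 (SE 0.24) and Ehhadh from -1.63 (SE 0.30) to -1.29 (SE 0.52). The calls ended through smaller folds and a median SE that rose from 0.15 to 0.22, the term resting on 1 IVF and 1 IVF+TEBx liver. Females alone gave 51 calls and males alone 2549.

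In biopsied livers cell cycle and erythroid genes were higher and fatty acid oxidation genes lower than in Natural livers. Cenpf rose from 98.5 ± 19.7 to 179 ± 35.1 CPM (n = 6 and 10, log2 change 0.83, SE 0.15, adjusted p = 0.00461), Mki67 by 0.82 and Top2a, a topoisomerase gene of dividing cells, by 0.59; 18 of 30 cell cycle genes rose, 30 adjusted over the list alone (camera adjusted p = 3.54e-19; adjusted p = 0.326 with an estimated correlation). Spta1 rose by 1.16, Epb42 by 0.98 and Kel by 0.86, as 12 of 16 erythroid genes (camera adjusted p = 4.96e-12; adjusted p = 0.270 with an estimated correlation). Fatty acid oxidation genes fell in 15 of 23 cases and none rose (18 adjusted over the list alone; camera adjusted p = 1.81e-11; adjusted p = 0.270 with an estimated correlation), with Ehhadh at 83.5 ± 37.5 CPM (-1.47, SE 0.29, adjusted p = 0.00668), Plin2 at -0.57 and Hadha at -0.43. Only 2 of 25 hepatocyte genes fell, Gys2 (-0.39) and Cyp3a11 (-1.31), and 2 of 27 respiratory chain genes, Cox4i1 and Cox5a (both -0.31). Apoc4, Apoe and Apoa2 fell by 0.87, 0.78 and 0.40. Meg3 (0.90), Rian (0.95), Mirg (0.85), Dlk1 (1.02) and Ampd3 (0.58) rose, with 5 of 30 maternally expressed genes higher. Serpina6 rose by 4.50, Hamp by 3.60, the bicarbonate transporter gene Slc4a5 by 2.64 and the glucose transporter gene Slc2a1 by 0.86. Of 16 interferon genes 0 fell (9 for IVF, median here -0.38), and of 20 hypoxia genes 0 (8). Gluconeogenesis had 0 of 20 (5) and acute phase genes 0 of 18 (5). IVF+TEBx against IVF called 0 genes, so no difference is shown. Named genes lay beyond the Natural median in 10 of 10 biopsied livers, or in 9 for Hamp.

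The biopsy comparison with Natural called 1270 liver genes, 751 higher and 519 lower. It called 14 without female Natural replicate 3, 6 without both livers that held pancreas transcripts, 8 with the erythroid score as a covariate and 2064 without female IVF+TEBx 5. With the term for the style of the library name it called 0, and Mki67 went from 0.82 (SE 0.17) to 0.33 (SE 0.25) and Ehhadh from -1.47 (SE 0.29) to -1.11 (SE 0.53). Females alone gave 20 calls and males alone 237. The effect of mode differed between the sexes for few genes, and each female Natural value there rests on 2 livers. Tiparp (chromosome 3, 65528410 to 65555518), a target of the aryl hydrocarbon receptor, differed between males and females by 1.82 for IVF (SE 0.27, adjusted p = 0.00943; -1.42 in females, 0.40 in males) and by 1.95 for IVF+TEBx (SE 0.26, adjusted p = 0.00196; -1.06 and 0.90). Ppp2r3a and Eepd1 differed for IVF+TEBx by 1.11 and 1.59 (adjusted p = 0.0363 for both). That count of 3 was 1 without any of female IVF+TEBx 1, 2 or 5, male IVF+TEBx 1, 4 or 5 or male Natural 1, 4 or 5, 7 without male Natural 3 and 26 without female Natural 1. For IVF the count of 1 was 2 without female Natural 1 and 4 without female Natural 3.

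Between IVF+TEBx and IVF livers, edgeR and limma-voom called 0 genes and DESeq2 6, with 689 of 15344 genes at an unadjusted p under 0.05 where chance gives 767. That unadjusted count was 1485 without male IVF 4, 1441 without female IVF+TEBx 1, 1906 in males alone and 319 in females alone. Camera called 19 lists, and 0 with an estimated correlation. Interferon genes had 10 of 16 higher adjusted over the list alone and a median of 0.89 (camera adjusted p = 4.61e-12; adjusted p = 0.505 with an estimated correlation). Isg15 stood at 29.4 ± 28.4 against 7.87 ± 7.22 CPM (log2 change 1.78, SE 0.53, adjusted p = 0.896, and 0.0179 over the list alone; above the IVF median in 8 of 10 livers), Ifit3 at 1.44, Irf7 at 1.14 and Usp18 at 0.81. Lists of hepatocyte maturation (median 0.37, camera adjusted p = 9.31e-06) and lipoproteins (0.21, 3.40e-06) had no member called (adjusted p = 0.505 with an estimated correlation for both), nor had hypoxia (0.27, 9.62e-07) and gluconeogenesis genes (0.31, 6.68e-06).

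The turn of the placental difference between E12.5 and E18.5 was itself tested. For IVF against Natural, 1482 of 17377 genes changed their log2 difference with age (798 upward, 684 downward), with 2290 in DESeq2 and 1151 in limma-voom. For IVF+TEBx against Natural it was 1712 (804 upward, 908 downward). With a term for the style of the library name at each age, added after seeing the data, the counts were 41 and 156. The median SE rose from 0.29 to 0.43 for IVF and from 0.30 to 0.43 for IVF+TEBx, and the median change of the genes called without the term went from 0.99 to 0.77 and from 0.84 to 0.75. The calls ended mostly through wider errors. The spongiotrophoblast median went from 2.74 to 2.77 and from 2.75 to 2.73, Prl8a8 from 4.67 (SE 0.91) to 4.53 (SE 1.25) for IVF, and Rsad2 from 2.06 (SE 0.30) to 1.36 (SE 0.41) for IVF+TEBx. Spongiotrophoblast genes moved upward in 17 of 22 cases for IVF and 16 of 22 for IVF+TEBx (19 and 18 adjusted over the list alone), with medians of 2.74 and 2.75 (camera adjusted p = 3.61e-15 and 1.93e-17; adjusted p = 0.405 and 0.204 with an estimated correlation). Slc22a18 moved by 3.22 (SE 0.51, adjusted p = 0.000194) for IVF, and Rsad2 (chromosome 12, 26442746 to 26456452) by 2.06 (SE 0.30, adjusted p = 3.07e-05) for IVF+TEBx. Kbtbd11 moved by 2.92 for IVF, the tyrosine phosphatase gene Ptprj by 1.38 and 1.47, Reps2 by 2.19 and 2.51 and the heparan sulfate synthesis gene Ext2 by 0.70 and 0.86 for IVF and IVF+TEBx. Pygo2 moved by -0.49 for IVF, and the RNA export gene Nxf1 and the RNA-binding gene Hnrnpa3 by -0.63 and -1.03 for IVF+TEBx. Heat-shock genes moved downward in 5 and 7 of 19 cases (camera adjusted p = 0.00280 and 0.00686; adjusted p = 0.533 and 0.617 with an estimated correlation). For IVF+TEBx against IVF, 0 genes changed with age in edgeR, DESeq2 and limma-voom, with 900 at an unadjusted p under 0.05.

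Both IVF arms were compared with the same Natural libraries, which alone makes their fold changes resemble each other. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.823 in E12.5 placentas, 0.729 in fetuses, 0.835 in E18.5 placentas and 0.845 in livers. Simulated unchanged groups against the same controls gave 0.515, 0.487, 0.481 and 0.671. The covariance was 0.33 against 0.091 simulated for E12.5 placentas, 0.146 against 0.041 for fetuses, 0.304 against 0.049 for E18.5 placentas and 0.242 against 0.072 for livers. With the Natural libraries split between the arms it was 0.339, 0.122, 0.279 and 0.156 in the same order, so the liver value is the one that stood well below the value with shared controls. Genes called in both comparisons with the same sign numbered 163 higher and 283 lower at E12.5, 626 and 453 in E18.5 placentas and 705 and 467 in livers. With the Natural libraries split, which leaves fewer per arm, r was 0.656, 0.661 and 0.453 there. Of only 3, 27 and 5 IVF calls, 0, 5 and 1 were shared higher and 0, 10 and 3 lower.

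The authors' deposited tables compare each sex separately. They hold more calls than the single-sex contrasts here, except where both have 0. In the authors' deposited table for female E12.5 placentas, IVF+TEBx against Natural has 2258 calls, of which 1007 are among the 1026 made here. In the authors' deposited table for male livers, IVF against Natural has 3912 calls against 2549 here, 2427 of them in both. For female livers the authors' deposited table of IVF+TEBx against Natural has 1631 calls against 20 here, and 1573 of the 1585 tested here had the same sign. The group means in the authors' deposited tables for livers match those of the deposited counts in only 5.62 to 15.5 percent of genes. For IVF+TEBx against IVF the authors' deposited tables have 46 calls in female and 0 in male E12.5 placentas, 48 higher and 137 lower genes in female and 0 in male fetuses, 0 and 1 in E18.5 placentas and 0 and 16 in livers.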

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

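The tests of the liver pattern, of shared name stems and of the style of the library names were chosen only after the result was seen; the other tests of this part were written before. Of 144 groups of libraries examined for a library far from the others, 17 held one where chance gives about 7.2.

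Spongiotrophoblast genes stood lower in IVF placentas at E12.5 and higher at E18.5, and the change between the ages differed by a test of the difference itself in 1482 genes for IVF and 1712 for IVF+TEBx. Other tissue in the libraries is argued against: with decidua and yolk sac scores as terms the score difference was -1.98 (SE 0.48) at E12.5, against -1.95 (SE 0.46) without them, and 1.19 (SE 0.34) at E18.5, against 1.03 (SE 0.34). An earlier stage at E12.5 is argued against too: with a stage score as a term the difference was -1.93 (SE 0.47), and the stage score itself differed by -0.04 (SE 0.18), where Natural placentas of the 2 days lie 8.82 (SE 0.12) apart. The style of the library name as the whole cause at E12.5 is argued against by a difference of -2.05 (SE 0.52) with that style as a term. At E18.5 the style cannot be told apart from mode: 0 of 10 Natural, 8 of 9 IVF and 9 of 10 IVF+TEBx placentas have a leading four-digit number, and the score difference was 1.09 (SE 0.72) with the term, no smaller but within 2 SE of 0. For the change of the score with age, a leading four-digit number as the whole cause is argued against, with the same limit on the rest of the names. The change was 3.14 (SE 0.89) with the term, against 2.98 (SE 0.57) without it. Most of it comes from E12.5, however, and the genes called went to 41 and 156 as errors widened. At E18.5 the stage score differed by -0.75 (SE 0.14), a sign the choice of its genes would give. Stage was not tested there. A difference in the parents or the culture of the embryos stays open, as untested.

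In livers, erythroid and cell cycle genes were higher and fatty acid oxidation genes lower in the IVF groups. Pancreas tissue in 2 Natural livers is argued against as the whole cause: without them the fatty acid oxidation score differed by -1.06 (SE 0.35), against -1.21 (SE 0.26) with them. A lower share of all liver parenchyma is argued against, since the erythroid score rose by 1.04 (SE 0.29) more than the mean of 4 other cell types, which stood at -0.25 (SE 0.13). More erythroid cells in the libraries stays open, as the fatty acid oxidation difference was -0.36 (SE 0.24) with the erythroid score as a term. The style of the library name cannot be told apart from mode in livers either: with it as a term the fatty acid oxidation difference was -0.52 (SE 0.43), the erythroid one 0.35 (SE 0.31), against 0.78 (SE 0.19), and the cell cycle one 0.10 (SE 0.20), against 0.60 (SE 0.14). A biological change in blood formation or hepatocytes was not tested.

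Cartilage genes were lower and early stage genes higher in IVF+TEBx fetuses. The part of the fetus that was sampled is argued against: with lens, heart and liver scores as terms the cartilage score differed by -0.86 (SE 0.17), against -0.80 (SE 0.13) without. An earlier stage of these fetuses cannot be told apart, since across 30 fetuses the residuals of the cartilage and early stage scores correlated with r = -0.23 (permutation p = 0.29; Spearman -0.16). Shared name stems cannot be told apart as a cause, since the 10 Natural fetuses carry only 2. With the stem as a random block the cartilage score gave -0.80 (SE 0.14). Of 21 splits of the 5 IVF+TEBx and 2 Natural stem means, 1 was as large, the real one and the fewest possible. The early stage score gave 0.55 (SE 0.24), and 2 of 21 splits as large. A biological effect of the biopsy was not tested further.

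Libraries far from the others of their group were, for Xist, the E12.5 male placentas IVF replicate 5 at 404 CPM (others 5.27 to 54.5) and IVF+TEBx replicate 3 at 136 CPM (0.472 to 30.3). The E18.5 male placentas IVF replicate 2 stood at 374 CPM (11.5 to 31.3) and IVF+TEBx replicate 1 at 81.2 CPM (13.3 to 17.9), and the female IVF fetus replicate 5 at 4270 CPM (1600 to 2440). For Ddx3y they were the E12.5 placentas male IVF replicate 5 at 34.9 CPM (97.3 to 109) and female IVF replicate 4 at 0.199 CPM (0 to 0.022), and the E18.5 placenta female IVF+TEBx replicate 2 at 0.196 CPM (0 to 0.0691). Among fetuses Ddx3y stood at 0.125 CPM in female IVF replicate 2 (0 to 0.0451), 0.041 CPM in female Natural replicate 1 (0 in the others) and 106 CPM in male IVF replicate 3 (84.5 to 87.2).

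Gene scores and totals far from the group were the yolk sac score of the E12.5 placenta male IVF replicate 4 at 7.14 (-1.54 to -1.03) and of the E18.5 placenta female IVF replicate 2 at 1.49 (6.94 to 7.40). The decidua score of the E18.5 placenta male Natural replicate 2 was 1.98 (3.14 to 3.53), the liver score of the fetus female Natural replicate 1 was 2.03 (5.47 to 6.47), and the pancreas score of the liver male Natural replicate 4 was 1.19 (-2.18 to -1.83). The fetus male IVF replicate 1 held 30.8 M counts (50.4 to 52.1).

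In livers the change differed between males and females, by a test of the difference itself, in 1 gene for IVF and 3 genes for IVF+TEBx. Chance cannot be excluded for these: 4 and 3 of 60 splits of the samples gave at least as many, and the highest other split gave 7 and 2060. The last is many times the real count and points to a structure of the samples.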

How the results depend on the processing

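The alternatives with tissue, organ or erythroid scores as covariates, with doubted libraries left out and, outside E12.5 placentas, with a term for the style of the library name were chosen only after the result was seen.

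Over the fits with both sexes and no single library left out, named genes that were called kept their direction and call in 278 of 320 values at E12.5 for IVF placentas, 535 of 579 for IVF+TEBx placentas and 276 of 329 for IVF+TEBx fetuses. In E18.5 placentas it was 527 of 660 and 457 of 570, and in livers 417 of 610 and 280 of 448. With 1 sex alone the values kept were 0 of 64 and 42 of 116, 16 of 66 in fetuses, 7 of 132 and 4 of 114 at E18.5 and 56 of 122 and 17 of 90 in livers. Genes that reversed did so in livers only, with the erythroid score as a covariate: Slco1b2 from -1.75 to 0.05, Trim71 from 1.83 to -0.09, Apoa4 for IVF+TEBx from -2.43 to 0.36 and Ces2a from -0.93 to 0.02. Cela2a for IVF+TEBx went from -4.79 to 1.42 without the 2 livers that held pancreas transcripts, which carried most of its counts. Depth limits the genes near the floor: with 8 to 21 counts over all libraries of an arm, a fold is not a bound.

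Counts with a change of at least 2-fold as well were 181 (of 501) and 577 (of 2387) in E12.5 placentas for IVF and IVF+TEBx against Natural, 0 (of 1) and 171 (of 598) in fetuses, 724 (of 2175) and 430 (of 1559) in E18.5 placentas and 425 (of 3101) and 132 (of 1270) in livers. The female contrast alone called 1 and 1026, 0 and 335, 59 and 61, and 51 and 20 in the same order, and 7 for IVF+TEBx against IVF in fetuses. The male contrast alone called 0 and 0, 0 and 0, 25 and 3, and 237 for IVF+TEBx in livers, with fewer samples in each.

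DESeq2 called 1561 for IVF in E12.5 placentas, 140 and 1103 in fetuses, 3295 and 2498 in E18.5 placentas and 2290 for the change of the IVF difference with age. For IVF+TEBx against IVF it called 12 in fetuses, 1 in E18.5 placentas and 6 in livers. For the difference between the sexes it called 1 and 1 in E12.5 placentas and 6 for IVF+TEBx against IVF, 3 and 32 in fetuses for IVF+TEBx against Natural and against IVF, 1 for IVF in E18.5 placentas, and 21 and 3 in livers for IVF+TEBx against Natural and against IVF. The cause was not tested. The single call of IVF fetuses was 2 in limma-voom and 0 with no filter on low counts, with the 2 arms alone, with name stems, with organ scores as covariates and with 1 doubted library left out; the 2 arms alone gave 1497 for IVF in E12.5 placentas. The cause was not tested.

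With name stems as a random block, limma-voom called 41 for IVF+TEBx in fetuses (614 without the block) and 1047 for IVF in E18.5 placentas (1642 without). Decidua and yolk sac scores as covariates gave 2390 and 4272 in E12.5 placentas and 2956 for IVF+TEBx at E18.5. The erythroid score gave 38 and 8 in livers. Other counts not printed here stayed within 1.5 times. A term for name style gave 627 and 2629 in E12.5 placentas, within 1.5 times. Only 323 of 501 calls and 21 of 32 named genes were kept for IVF, against 1979 of 2387 and 53 of 58 for IVF+TEBx. In fetuses it gave 0 and 631 (587 of 598 kept), but sets only 1 IVF fetus apart and cannot test IVF+TEBx. It gave 0 and 10 in E18.5 placentas, 0 and 0 in livers and 41 and 156 for the change with age. In each E18.5 tissue only 1 IVF and 1 IVF+TEBx library share the Natural style, so the term rests on these and widens the errors. Why folds shrank was not tested.

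Leaving out 3 doubted E12.5 placentas gave 2015 and 1532, and leaving out 2 Natural livers gave 239 and 6, with a lone female Natural liver assumed to vary like the other groups. The cause was not tested.

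With an estimated correlation between genes in camera, the lists called went to 0 from 8, 7 and 4 in E12.5 placentas, from 15 and 10 in fetuses for IVF against Natural and IVF+TEBx against IVF, from 12, 14 and 7 in E18.5 placentas and from 16, 14 and 19 in livers. For IVF+TEBx against Natural in fetuses they went from 16 to 1. A correlation above the preset 0.01 widens the spread of a list's mean, and most estimates lay above it; for maternally expressed imprinted genes in livers they were 0.006 and 0.007.

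Replicate numbers do not pair the samples: the correlation of same-numbered libraries had medians of -0.11, 0, 0.02 and -0.04, with 6 of 23, 13 of 28, 8 of 26 and 3 of 20 pairs over 0.1 in E12.5 placentas, fetuses, E18.5 placentas and livers, and 3, 5, 7 and 5 libraries correlated best with their own number. With the number as a replicate block, IVF gave 257 in E12.5 placentas, 0 in fetuses and 1432 in E18.5 placentas, IVF+TEBx gave 762 in livers, and camera called 7 lists instead of 4 for IVF+TEBx against IVF in E12.5 placentas.

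Leaving out each library in turn gave 53 to 832 and 929 to 3578 calls in E12.5 placentas for IVF and IVF+TEBx against Natural, 0 to 6 and 296 to 783 in fetuses, 1061 to 2748 and 645 to 3068 in E18.5 placentas and 398 to 4095 and 14 to 2064 in livers. IVF+TEBx against IVF ranged from 0 to 4 in fetuses and 0 to 0 elsewhere. The difference between the sexes ranged from 1 to 4 and 1 to 26 in livers against Natural and 0 to 12 for IVF+TEBx against IVF in E12.5 placentas. No named gene reversed, but calls were lost: those kept were 354 of 576 and 859 of 928 in E12.5 placentas, 566 of 660 in fetuses for IVF+TEBx, 1150 of 1254 and 957 of 1140 in E18.5 placentas and 857 of 915 and 612 of 720 in livers. The fewest kept were 6 of 32 for IVF in E12.5 placentas (without male Natural replicate 2), 34 of 57 for IVF+TEBx in E18.5 placentas (male IVF+TEBx 4) and, without female Natural 3, 17 of 61 and 1 of 45 in livers.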

Other observations

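All tests of this part compare other splits of the same samples and were planned; the term for name style was added after seeing the data outside E12.5 placentas.

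Further genes and groups lay outside the main patterns. In IVF livers the hypoxia genes Vegfa (-0.66), Aldoa (-0.69) and Bnip3 (-0.88) fell, as 8 of 20 genes of hypoxia and glycolysis, while 1 rose (adjusted p = 0.465 with an estimated correlation). Those 3 genes lay beyond the Natural median in 8 of 9 livers. Of the same list 5 rose in IVF+TEBx placentas at E12.5, and 4 and 3 rose at E18.5 for IVF and IVF+TEBx. The acute phase genes Apcs and Il1rn fell by 1.54 and 1.43, as 5 of 18. The esterase gene Ces2a fell by 1.08. The RNA regulator Trim71 of early development rose by 1.83. The imprinted Sfmbt2 fell by 1.81 in IVF livers and by 1.63 in biopsied livers.

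In E18.5 placentas, the interferon gene Oasl2 fell by 0.59 for IVF and 0.51 for IVF+TEBx while Rsad2 rose. Mki67 rose by 0.79 for IVF, and Nr4a1, an immediate early gene, fell by 0.67 and 0.76. Chil3 of myeloid cells fell by 2.95 and 3.20. In biopsied fetuses the germline gene Slc25a31 fell by 1.90 and the maternally expressed Klf14 by 0.80, and the heat-shock gene Hspa1a by 2.2, beyond the Natural median in 8 of 10 fetuses.

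Chance as the source of the counts was tested with splits of the samples, 60 per comparison and 25 for the change with age, the real one included. If libraries are independent, chance is made less likely where only the real split reached the count. These were 501 for IVF in E12.5 placentas (highest other split 0), 2387 for IVF+TEBx there (1244) and 598 for IVF+TEBx in fetuses (0). They were 2175 and 1559 in E18.5 placentas (2031 and 10) and 3101 and 1270 in livers (2988 and 458). The change with age, 1482 and 1712 genes, was reached by 1 of 25 splits each, the real one (highest other 23 and 102). The splits did not keep libraries of a shared name stem together. For IVF+TEBx against Natural in fetuses, limma-voom called 614 genes without and 41 with stems as a block. Nor do the splits separate mode from the style of the library name. A term for that style left 0, 10, 0 and 0 calls at E18.5 and 41 and 156 for the change with age. For IVF in fetuses 2 of 60 splits gave 1 gene or more, and the highest other split gave 1.

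Where the real count is 0 every split reaches it, so this test was settled in advance and says nothing on chance. For IVF+TEBx against IVF that is 60 of 60, with highest other splits of 1599 in E12.5 placentas, 171 in fetuses, 1851 in E18.5 placentas and 1 in livers, and 25 of 25 for the change with age (3). For the difference between the sexes it is 60 of 60 as well. The highest other splits there were 1, 1 and 3789 in E12.5 placentas, 205, 1173 and 164 in fetuses and 1552, 2046 and 10 in E18.5 placentas for IVF against Natural, IVF+TEBx against Natural and IVF+TEBx against IVF, and 1 in livers for the last of these. Splits that call many genes where the real one calls 0 point to a structure of the samples other than mode and sex.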
